A study of Candidatus Pelagibacter ubique HTCC1062 and gamma proteobacterium HTCC2207 and Ruegeria pomeroyi DSS-3 with 44 samples.

How the data were processed

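RNA-seq read counts were analysed from batch cultures of 4 heterotrophic marine bacteria. Per the labels, these are Candidatus Pelagibacter ubique HTCC1062 (here Pelagibacter, an alphaproteobacterium with a very small genome), the SAR92 gammaproteobacterium HTCC2207 (SAR92), the alphaproteobacterium Ruegeria pomeroyi DSS-3 (Ruegeria) and the flavobacterium Polaribacter sp. MED152 (MED152). Per the labels' protocols, cultures grew at 19 °C in the dark with aeration, cells were caught on 0.2 µm filters, RNA was extracted with a combined DNA and RNA kit, ribosomal RNA was depleted with Ribo-Zero and libraries were made with a TruSeq RNA kit. Each sample is given as rapid or slow growth, and the series' design text states that each phase was sampled at more than 1 time.

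The 5 deposited tables hold, for each annotated gene and each predicted RNA, raw counts per library, which the authors left unnormalized per the file headers. The authors also deposited a p-value and a q-value per gene for their own comparison of rapid with slow growth, per the file headers. The aligner, the counting program, the use of strand, the test behind these p-values and the genome builds are not given in the sources used here. Coordinates are therefore printed as the tables give them, 1-based and without a build, and none are printed for SAR92, whose positions restart on contigs that the table does not name. A further 112 columns of normalized values per library were not used. Coordinates and product names come from the tables.

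The count columns carry library numbers that match each strain's phases but no time point or replicate number, so all libraries of a phase were treated as 1 group and no time point was compared. Of the 44 samples, 43 were used: Ruegeria libraries 141 and 145 hold identical counts for every gene and were counted as 1 sample. This left 6 rapid and 6 slow libraries for Pelagibacter, 3 and 9 for SAR92, 6 and 5 for Ruegeria, and 4 and 4 for MED152. For SAR92, the sample titles give 1 rapid and 3 slow time points, whereas the design text gives an equal number for both phases. The labels were followed. No label says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

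Features that name no gene, the predicted RNAs, were left out of library sizes and tests. They numbered 7 in Pelagibacter, 60 in SAR92, 1150 in Ruegeria and 62 in MED152, and held a mean of 2.34%, 1.08%, 27.8% and 2.36% of counts. No feature named a ribosomal or transfer RNA gene. Gene counts per library ran from 1001444 to 1616240 in Pelagibacter, 678378 to 1130443 in SAR92, 102682 to 869697 in Ruegeria and 242916 to 1845608 in MED152. Genes were filtered with filterByExpr by phase, which left 1243, 2229, 3529 and 2257 genes.

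Each strain was fitted alone with edgeR 4.0.16 in R 4.3.3: TMM factors, robust dispersions and the quasi-likelihood F test of slow over rapid growth, with Benjamini-Hochberg adjustment. Genes with an adjusted p under 0.05 were called. Every log2 fold change is slow over rapid growth, its standard error is the fold change divided by the square root of F, and every adjusted p of a gene comes from this test unless another tool is named. Levels are CPM of gene counts with TMM-scaled library sizes, as mean ± SD. Tested on simulated counts with 200 changed genes, 50 at each fold, the fit called 92% of 1.5-fold and 100% of 2-fold changes in Pelagibacter and 74% and 94% in SAR92. In Ruegeria it called 14% of 1.5-fold, 64% of 2-fold and 90% of 4-fold changes, and in MED152 12%, 54% and 98%. Between 0.245% and 0.444% of unchanged genes were called. The simulated counts were independent between genes, with few genes changed and rises and falls balanced. These rates need not hold where most genes change or genes vary together, as in Ruegeria.

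A total of 34 lists of genes by function were fixed as word patterns on product names and symbols before the data were examined. Lists with at least 3 tested members were tested with limma 3.58.1's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Beside the count of members called over all genes, a count is given adjusted over the list alone. A list of transfer RNA genes matched only proteins that process transfer RNA and is void under its name. Differences between strains were tested with limma on list scores, the mean log2 CPM of a list's members per library with a prior count of 2, as the interaction of strain and phase with Benjamini-Hochberg adjustment over 32 lists.

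Named genes followed a rule fixed before the data were examined. It takes, per strain, the 8 largest rises and 8 largest falls among called genes with a product annotation and a mean of at least 20 counts whose sign held without each library in turn, the 2 largest of each sign with any annotation, the 2 members of each called list with the smallest p, and every rhodopsin, groEL, dnaK, rpoD, ammonium transporter, glutamine synthetase and elongation factor Tu gene. Leaving out each library stands in for leaving out each replicate number, which the columns do not carry. To compare strains, 20 random draws of 3 rapid and 3 slow libraries, and of 2 and 2, were thinned to a mean of 24 counts per gene. This equals the mean and not the number of testable genes, which was lowest in Pelagibacter, where 1 gene takes much of the counts. Shares of counts were compared with exact permutation tests, two-sided, and correlations with 100000 permutations. The libraries were also regrouped in up to 100 other splits per strain.

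Alternatives were DESeq2 1.42.0, size factors by relative log expression (RLE), library totals with no factors, no filter or a mean of at least 20 counts, thinning to the smallest library, predicted RNAs kept, both identical libraries kept, the Ruegeria chromosome and plasmid normalized separately, each library left out, and the libraries under 0.5 of their strain's median gene count left out (Ruegeria 137 and 141, MED152 173 and 193). Scaling by library totals shifted the median log2 fold change of all genes by 0.21 in Pelagibacter, −0.07 in SAR92, −0.34 in Ruegeria and 0.12 in MED152 against TMM. Figures were drawn with matplotlib 3.10.9.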

Results

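To examine transcriptional control in Pelagibacter beside other marine bacteria, the transcriptomes of 4 strains were compared between an early phase of rapid growth and the slower growth after it. The 43 libraries used comprised 6 rapid and 6 slow ones of Pelagibacter, 3 and 9 of SAR92, 6 and 5 of Ruegeria, and 4 and 4 of MED152. Slow Ruegeria libraries 141 and 145 differed by less than the sampling noise, holding identical counts, and were counted as 1 sample. The tables list 1354 genes for Pelagibacter, 2388 for SAR92, 4278 for Ruegeria and 2635 for MED152. The mean count per gene ran from 739.6 to 1194 over the Pelagibacter libraries, from 284.1 to 473.4 in SAR92, from 24 to 203.3 in Ruegeria and from 92.2 to 700.4 in MED152. A single gene for a putative porin, SAR11_0359, took between 22.55% and 34.35% of all gene counts in each Pelagibacter library.

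In Pelagibacter few transcripts were called between phases, and nearly all differences called were small. Among genes with a product annotation the largest fall was in isocitrate lyase, the first enzyme of the glyoxylate bypass: aceA (SAR11_1240, 1182407 to 1183681, minus strand) had 288 ± 70 CPM in rapid growth and 132 ± 18 CPM in slow growth (SD, n = 6 and 6). This was a log2 fold change of −1.14 ± 0.16 (SE; adjusted p = 0.0019), with all 6 slow libraries below every rapid one. The hypothetical gene next to it, SAR11_1241, fell by 1.19 ± 0.16 on the log2 scale. Falls in other annotated genes were smaller. The rhodopsin SAR11_0625, a light-driven proton pump gene, fell by 0.43 ± 0.09, the Na+/solute symporter gene yjcG by 0.41 ± 0.09, and the polyamine-binding protein gene potD by 0.40 ± 0.09. The ABC transporter gene yhdW fell by 0.39 ± 0.09 and the ammonium transporter amt (SAR11_1310) by 0.40 ± 0.08. Each of these 5 was lower in 6 of 6 slow libraries, with adjusted p between 0.0019 and 0.0029. The other 3 ammonium transporter genes, SAR11_0049 at 0.14 ± 0.06, SAR11_0050 at −0.16 ± 0.06 and amtB at −0.00 ± 0.07, did not pass. Glutamine synthetase I (glnA) fell by 0.24 ± 0.07 (adjusted p = 0.034), a call that ended without library 6, 18, 22, 26, 28 or 32 (adjusted p up to 0.107).

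Among called genes the largest rises in Pelagibacter were in a pair of neighbours, the hypothetical gene SAR11_1163 (log2 fold change 0.71 ± 0.12, adjusted p = 0.0022) and the possible lipoprotein SAR11_1164 (0.67 ± 0.14, adjusted p = 0.011), both higher in 6 of 6 slow libraries. The response regulator chvI (0.47 ± 0.08) and the small heat shock protein gene ibpA (0.46 ± 0.09) rose in 6 of 6 libraries. So did accA of acetyl-CoA carboxylase, which starts fatty acid synthesis (0.46 ± 0.07, adjusted p = 6.7e-05), and murA, which starts peptidoglycan synthesis (0.45 ± 0.09). Of 17 chaperones and heat shock proteases 4 rose, among them ibpA and the protease gene lon (0.25 ± 0.06), and 13 did not pass (7 rose adjusted over the list alone; adjusted p = 0.468 with an estimated correlation). The main chaperone genes groEL (0.13 ± 0.09, adjusted p = 0.47) and dnaK (0.14 ± 0.09, adjusted p = 0.40) did not pass. Of 5 two-component genes 2 rose, chvI and the response regulator SAR11_0203 (0.38 ± 0.07), with the same 2 adjusted over the list alone (adjusted p = 0.435 with an estimated correlation). Of 53 ribosomal protein genes 3 fell, including rplL (−0.29 ± 0.06) and rplQ (−0.22 ± 0.06), and 50 did not pass (3 fell adjusted over the list alone). The list's median was −0.09, and 0.12 when scaled by library totals (adjusted p = 0.556 with an estimated correlation). Of 8 ATP synthase genes 1 fell, atpC (−0.26 ± 0.07), against 6 adjusted over the list alone, with a median of −0.20, and 0.02 by library totals (adjusted p = 0.435 with an estimated correlation). Of 17 type IV pilus genes 2 fell (3 adjusted over the list alone), with a median of −0.09, and 0.12 by library totals (adjusted p = 0.468 with an estimated correlation). Of 3 TRAP transporter genes 2 fell (2 adjusted over the list alone; adjusted p = 0.435 with an estimated correlation). For 6 iron acquisition genes the median was 0.49; edgeR called 0 over all genes, with 3 at an unadjusted p under the threshold and 2 by DESeq2, and 3 rose adjusted over the list alone. The adjusted p was 0.47 with an estimated correlation. Among them sfuC (SAR11_1238), named after its values were seen, had 2.15 ± 0.73 (adjusted p = 0.125).

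In all, 33 Pelagibacter genes rose and 42 fell of 1243 tested (6.03%), and 2, aceA and SAR11_1241, changed by at least 2-fold. More may differ: 249 genes had an unadjusted p under the threshold by edgeR, and 408 had an authors' q-value under 0.05. With library totals in place of TMM factors the split was 264 higher and 6 lower. With an estimated correlation camera called 0 of the 7 lists, with 2 of the 26 tested at an unadjusted p under the threshold. By fry 2 of the 7 were called, two-component systems and TRAP transporters. Without slow library 32, 20 genes rose and camera called 3 lists. Without rapid library 10, 27 genes fell and it called 4 lists, as it did without slow library 36. Of the 29 called genes among those picked by the naming rule, 20 were called without each library in turn. The other 9 include glnA, both pilus genes (SAR11_0071 and SAR11_0053), 1 of the 2 TRAP transporter genes (SAR11_0266), and atpC, whose call ended without library 2, 6, 10 or 32.

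**Figure D1:**
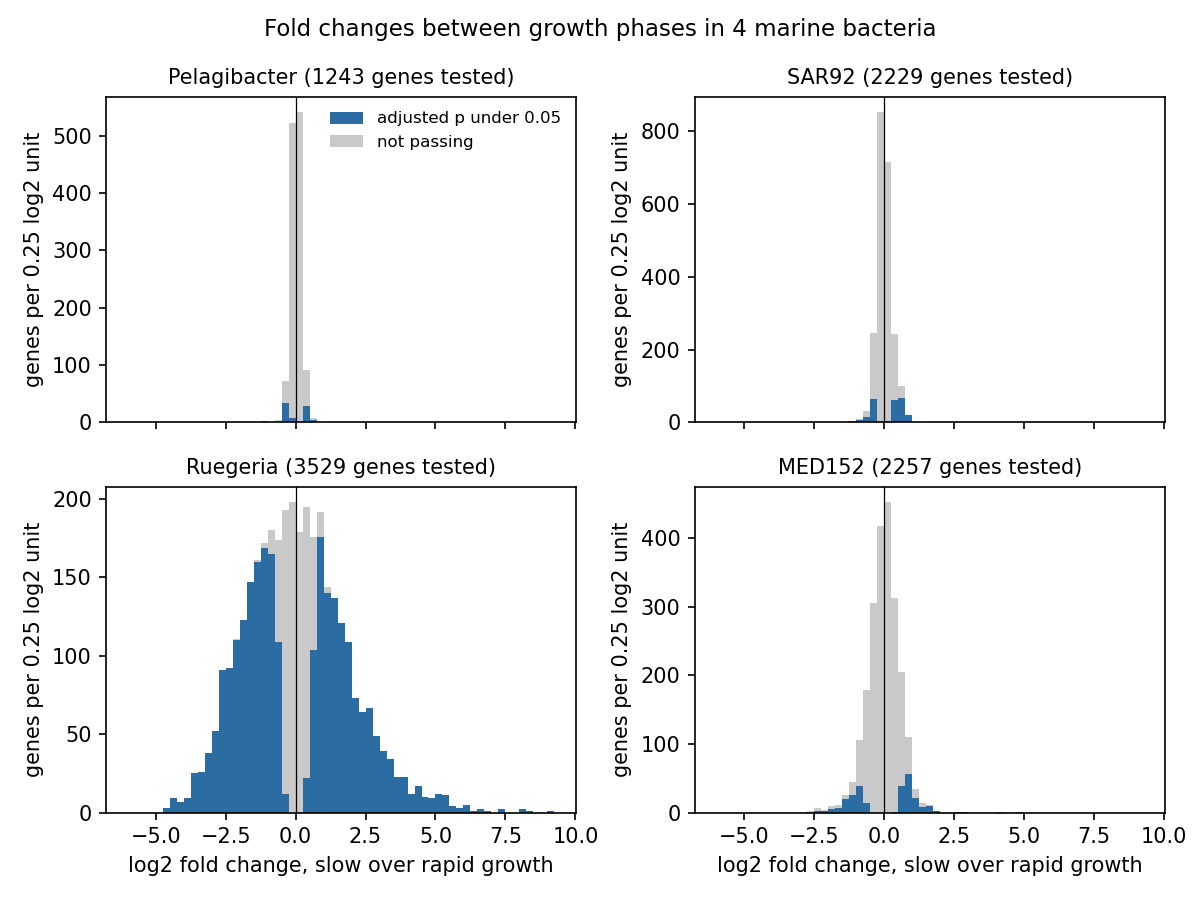
Histograms of the log2 fold change of every tested gene, slow over rapid growth, for the 4 strains (x axis in log2 units, y axis genes per bin), with genes passing the adjusted threshold in blue and the others in grey. The interquartile range is 0.20 in Pelagibacter, 0.31 in SAR92, 2.43 in Ruegeria and 0.68 in MED152.

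In SAR92, of 52 ribosomal protein genes 46 rose and 6 did not pass (51 rose adjusted over the list alone), with a median log2 fold change of 0.67 (adjusted p = 0.590 with an estimated correlation). Among them the genes of proteins L28 (GB2207_09216, 0.89 ± 0.20, adjusted p = 0.019) and S15 (GB2207_10688, 0.88 ± 0.19, adjusted p = 0.015) were higher in 8 of 9 and 9 of 9 slow libraries. Elongation factor Tu, which brings aminoacyl-tRNA to the ribosome, rose from 6907 ± 568 to 13220 ± 4269 CPM (tuf, GB2207_07746, 0.94 ± 0.25, n = 3 and 9, adjusted p = 0.031). A short gene with the same annotation, GB2207_07676, rose by 0.83 ± 0.26, and reads may be shared between these copies. SecE of the protein translocase (0.94 ± 0.25), the ribosome maturation factor RimP (0.93 ± 0.23) and elongation factor P (0.86 ± 0.23) rose as well. Of 38 translation factor and tRNA synthetase genes 9 rose and 29 did not pass (13 rose adjusted over the list alone; adjusted p = 0.724 with an estimated correlation). All 3 RNA polymerase core genes rose (3 adjusted over the list alone), with a median of 0.52 (adjusted p = 0.590 with an estimated correlation). The main sigma factor RpoD rose by 0.41 ± 0.10. Of 12 respiratory chain genes 3 rose (8 adjusted over the list alone; adjusted p = 0.724 with an estimated correlation). All 3 encode subunits of the sodium-translocating NADH-quinone reductase, such as GB2207_03257 (0.41 ± 0.10).

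Among the named genes that fell in SAR92, an oxidoreductase gene, GB2207_05554, fell by 1.48 ± 0.23 (adjusted p = 0.0035, lower in 9 of 9 slow libraries), and its neighbour GB2207_05559, a hypothetical protein, by 1.48 ± 0.25. A FAD-linked oxidase, GB2207_05544, fell by 1.03 ± 0.17 and a glycerol-3-phosphate dehydrogenase, GB2207_05539, by 1.07 ± 0.19. The 5 acyl-CoA dehydrogenases among the named genes, enzymes of fatty acid oxidation, fell by between 0.95 and 1.19. Of these, GB2207_01027 (−1.07 ± 0.15, adjusted p = 0.0027) and GB2207_01032 (−0.96 ± 0.19, adjusted p = 0.0085) were lower in 9 of 9 slow libraries, whereas GB2207_00220 and GB2207_00225 were lower in 4 of 9, with rapid levels of 222 ± 188 and 157 ± 130 CPM. The calls of 3 of the 5 ended without rapid library 44, which gave −0.12 for GB2207_00220, −0.26 for GB2207_00225 and −0.45 for GB2207_02577 (adjusted p = 0.667, 0.476 and 0.105). The call of GB2207_00225 also ended without library 76, 84 or 88, and that of GB2207_00220 without any library but 48 and 52. Phytoene dehydrogenase, an enzyme of carotenoid synthesis, was the 1 of 3 light and carotenoid genes that fell (GB2207_10301, −0.46 ± 0.08, 1 adjusted over the list alone; adjusted p = 0.590 with an estimated correlation). Of 34 flagellar and chemotaxis genes, with a median of −0.26, 1 rose and 1 fell, the latter FlhB of the export apparatus (−0.37 ± 0.11). Adjusted over the list alone, 1 rose (adjusted p = 0.816 with an estimated correlation).

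In all, 154 SAR92 genes rose and 97 fell of 2229 tested (11.3%), 8 of them by at least 2-fold. The split was 111 higher and 154 lower with library totals. The counts moved with single libraries, to 92 and 40 without rapid library 44, 17 and 42 without rapid library 48, and 5 and 25 without rapid library 52. Without slow library 72, 76, 80 or 88, 94, 94, 80 and 89 genes rose and 70, 63, 70 and 71 fell. Camera called 3 lists without library 52. Of the 30 named calls 6 held without each library in turn (GB2207_05554, GB2207_05544, GB2207_05559, GB2207_01027, GB2207_01032 and GB2207_10301). With an estimated correlation camera called 0 of the 6 lists, with 0 of the 30 tested at an unadjusted p under the threshold. By fry 3 of these 6 were called, ribosomal proteins, RNA polymerase and carotenoids, and 3 other lists, TRAP transporters, TonB-dependent uptake and peptidases.

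In Ruegeria most of the transcriptome differed between phases. Of 54 ribosomal protein genes 53 fell (53 adjusted over the list alone), with a median log2 fold change of −2.90 (adjusted p = 0.258 with an estimated correlation). The gene of protein L13 (rplM, SPO1691, chromosome 1797668 to 1798126, plus strand) went from 1071 ± 110 to 41 ± 21 CPM (n = 6 and 5). This was a change of −4.62 ± 0.28 (adjusted p = 4.1e-09), and rpsT (SPO0148) fell by 4.35 ± 0.37. Of 38 translation factor and tRNA synthetase genes 35 fell and 2 rose (35 and 2 adjusted over the list alone), with aspS at −3.13 ± 0.20. All 4 RNA polymerase core genes fell (4 adjusted over the list alone), with rpoA at −2.54 ± 0.20. The adjusted p with an estimated correlation was 0.258 for both lists. All 10 ATP synthase genes fell (10 adjusted over the list alone), with atpI at −3.97 ± 0.23 and atpB at −3.70 ± 0.30 (adjusted p = 0.258 with an estimated correlation). Of 43 respiratory chain genes 35 fell and 1 rose, of 16 TCA cycle genes 13 fell and 1 rose, and of 22 glycolysis and Entner-Doudoroff genes 19 fell and 1 rose, with the same counts adjusted over the list alone. The adjusted p with an estimated correlation was 0.258, 0.319 and 0.258. Examples are the cytochrome b gene petB (−2.43 ± 0.21), malate dehydrogenase (mdh, −3.51 ± 0.31) and phosphoglycerate kinase (pgk, −2.73 ± 0.22). Both elongation factor Tu genes fell, tuf-1 by 2.03 ± 0.29 and tuf-2 by 2.02 ± 0.29, though reads may be split between these near-identical copies.

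Of 20 flagellar and chemotaxis genes in Ruegeria 18 rose (18 adjusted over the list alone), with a median of 3.28 (adjusted p = 0.206 with an estimated correlation). The stator gene motB (SPO0191, chromosome 209006 to 209863, plus strand) rose from 5.9 ± 3.2 to 420 ± 39 CPM (6.04 ± 0.26, adjusted p = 1.5e-10, 5 of 5 slow libraries above all rapid ones) and the adjacent hook gene FlgE (SPO0192) by 5.13 ± 0.26. The quorum-sensing regulator genes luxR-1 (SPO0371, 5.23 ± 0.21) and luxR-2 (SPO2286, 2.79 ± 0.20) rose. Of 176 transcriptional regulators 85 rose and 29 fell (82 and 25 adjusted over the list alone; adjusted p = 0.258 with an estimated correlation). Of 36 two-component genes 21 rose and 9 fell (21 and 9 adjusted over the list alone), with the response regulator SPO0931 at 5.32 ± 0.30 (adjusted p = 0.206 with an estimated correlation for the list). Of 8 sigma factors 5 rose (5 adjusted over the list alone), among them rpoH-1, the heat shock sigma factor (3.20 ± 0.32), and SPOA0392 on the plasmid (3.57 ± 0.31), while rpoD did not pass (0.33 ± 0.26, adjusted p = 0.26). For the list the adjusted p was 0.258 with an estimated correlation. All 19 genes of sulfur and carbon monoxide oxidation rose (19 adjusted over the list alone), with a median of 1.87 and the carbon monoxide dehydrogenase genes coxS-1 and SPO1520 at 2.75 ± 0.21 and 2.95 ± 0.20 (adjusted p = 0.0275 with an estimated correlation for the list). Of 9 phage and gene transfer agent genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), with a major capsid protein, SPO2261, at 4.20 ± 0.48 (adjusted p = 0.206 with an estimated correlation for the list). Among the largest single rises were the EAL domain gene SPO0327 (6.17 ± 0.30), from a family that degrades cyclic di-GMP, the DNA processing protein gene DprA (SPO3078, 6.04 ± 0.28) and a regulator gene, SPO1252a (6.72 ± 0.51). The anti-anti-sigma factor SPO3409 had 1 count over the 6 rapid libraries and 88, 91, 59, 29 and 11 counts in the 5 slow ones. The chaperone genes moved apart, with groEL at −1.82 ± 0.28 and dnaK at 0.55 ± 0.18 (adjusted p = 0.012).

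In all, 1274 Ruegeria genes rose and 1347 fell of 3529 tested (74.3%), and 2033 (57.6%) changed by at least 2-fold. The calls of 50 of the 52 named genes held without each library in turn. Scaling by library totals gave 1021 higher and 1588 lower. Of the 13 called lists, sulfur and carbon monoxide oxidation was the 1 called with an estimated correlation. By fry all 13 were called, among 24 lists of 30 tested. As fry tests a list on its own, it passes readily where most genes change. Slow libraries 137 and 141, the least deep, also stood apart in the share of gene counts from the plasmid, 7.72% and 8.04% against 4.17% to 4.89% in the other 9. Without both, 1355 genes rose, 1398 fell and 11 of the 13 lists held.

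In MED152 a TonB-dependent channel gene, MED152_01605 (342814 to 344718, plus strand), from a family of outer membrane receptors, rose from 48 ± 16 to 1452 ± 563 CPM (n = 4 and 4). This was a log2 fold change of 4.89 ± 0.35 (adjusted p = 7.1e-05, 4 of 4 slow libraries above all rapid ones). Other rises included a second TonB-dependent channel (MED152_11214, 1.57 ± 0.32), the alginate lyase alyA3 (1.66 ± 0.34), the sigma factor MED152_09710 (1.80 ± 0.37) and acetolactate synthase (ilvB1, 1.74 ± 0.39). TonB-dependent genes did not rise as a list: of 34 tested 3 rose and 4 fell (4 and 6 adjusted over the list alone). Their median was −0.42, and camera did not call the list (adjusted p = 0.449). Of 4 storage polymer genes 1 rose, the polyphosphate kinase MED152_05065 (1.23 ± 0.20; 4 adjusted over the list alone; adjusted p = 0.788 with an estimated correlation). Aspartokinase (lysC) fell by 2.26 ± 0.41, diaminopimelate decarboxylase (lysA) by 2.15 ± 0.44 and aspartate-semialdehyde dehydrogenase (asd) by 1.95 ± 0.48 (adjusted p = 0.017, 0.021 and 0.035, lower in 4 of 4 slow libraries). All 3 of these calls ended without slow library 185 or 193, those of lysA and asd also without rapid library 157, and that of asd without slow library 173 or 181. Carbamoyl-phosphate synthase (carB) fell by 1.85 ± 0.29, the glutamine synthetase glnN by 1.01 ± 0.29, and groEL to 0.501 times its rapid level.

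Of 55 ribosomal protein genes in MED152 8 fell and 47 did not pass (35 fell adjusted over the list alone), with a median of −0.83 and rpsJ at −1.34 ± 0.31 (adjusted p = 0.788 with an estimated correlation for the list). Of 8 ATP synthase genes 2 fell (8 adjusted over the list alone), with atpH at −0.93 ± 0.22 (adjusted p = 0.788 with an estimated correlation for the list). Proteorhodopsin, the light-driven proton pump, did not pass (MED152_12844, 0.14 ± 0.45, adjusted p = 0.87) at 28 ± 11 CPM in rapid and 29 ± 16 CPM in slow growth, nor did tuf (−0.57 ± 0.39, adjusted p = 0.34). With an estimated correlation camera called 0 of the 3 lists, with 1 of the 28 tested at an unadjusted p under the threshold. By fry 1 of these 3 was called, storage polymers, and 2 other lists, ABC transporters and the void transfer RNA list.

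In all, 140 MED152 genes rose and 116 fell of 2257 tested (11.3%), 109 of them (4.83%) by at least 2-fold. The calls depended on single libraries: without slow library 185 or 193, edgeR called 3 genes higher and 0 lower. There were then 552 and 609 genes at an unadjusted p under the threshold, 262 and 314 of them lower, and 100 and 126 lower by DESeq2. The counts were 15 and 17 without rapid library 157, 51 and 49 without library 149, and 57 and 39 without library 173. Among the 25 named calls, MED152_01605 was the 1 that held without each library in turn.

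Phase effects on the lists were then compared between strains. The ribosomal protein score fell by 2.98 ± 0.20 (SE) in Ruegeria and by 0.77 ± 0.31 in MED152, rose by 0.63 ± 0.18 in SAR92 and changed by −0.09 ± 0.04 in Pelagibacter. This interaction of strain and phase had an adjusted p of 5.7e-16. Slow libraries lay below all rapid ones in 5 of 5 cases in Ruegeria, 4 of 4 in MED152 and 3 of 6 in Pelagibacter, and above all rapid ones in 8 of 9 in SAR92. ATP synthase scores changed by −3.26 ± 0.31 in Ruegeria, −0.78 ± 0.23 in MED152, −0.18 ± 0.06 in Pelagibacter and 0.19 ± 0.13 in SAR92 (adjusted p = 6.5e-15). Of 32 lists tested, 26 differed between strains, and 12 of 29 without Ruegeria. With libraries weighted by strain 26 lists differed. With phases drawn at random within strains up to 21 lists passed. Unbalanced draws carry part of the real phase effects, so they cannot tell whether the adjusted p-values of this interaction overstate the evidence. Chaperones, oxidative stress defence, starvation and general stress, osmolyte and one-carbon catabolism, ABC transporters and TonB-dependent uptake did not pass, with adjusted p of 0.11, 0.31, 0.12, 0.31, 0.32 and 0.70. Without Ruegeria the same test did pass for ABC transporters (adjusted p = 0.0297), which are among the 12.

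**Figure D2:**
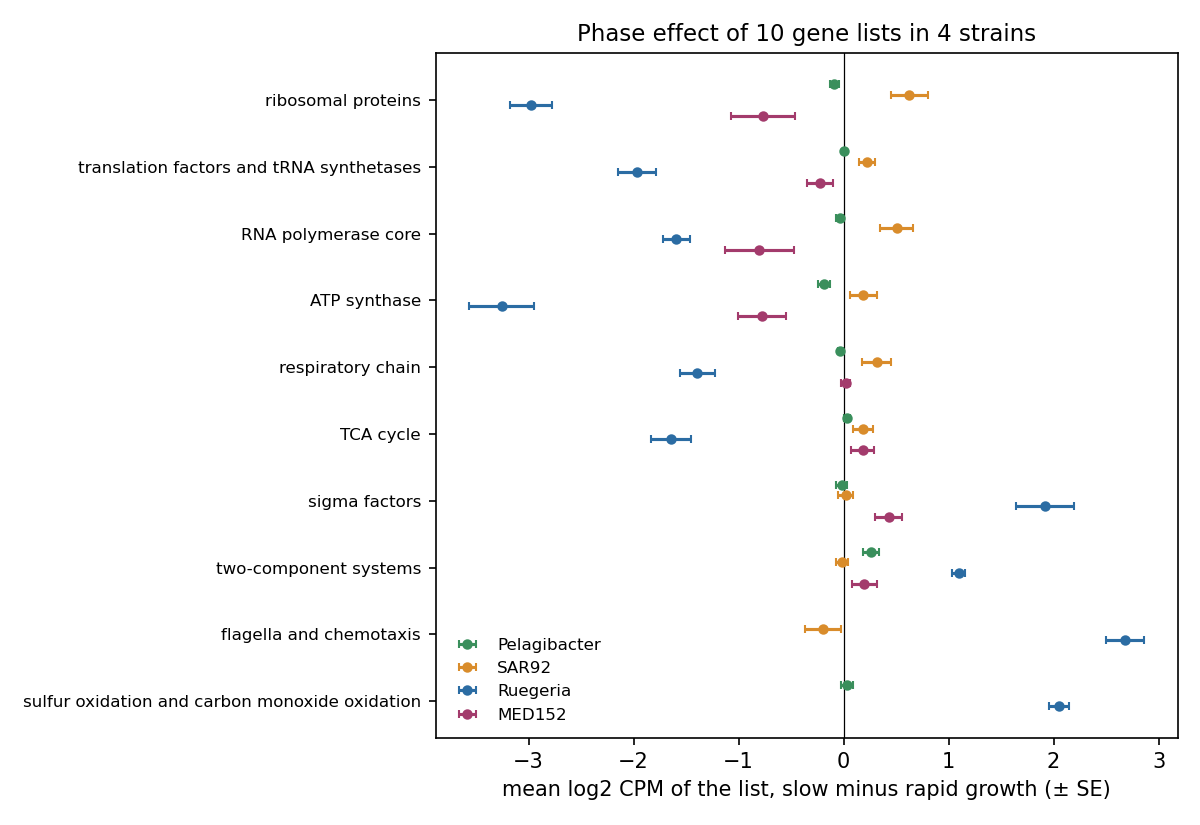
Phase effect of 10 gene lists per strain as the difference in mean log2 CPM between slow and rapid libraries (points, x axis in log2 units) with standard errors (bars), where a list has at least 3 tested members. Ruegeria points lie farthest from 0, from −3.26 for ATP synthase to 2.68 for flagella and chemotaxis.

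**Figure D3:**
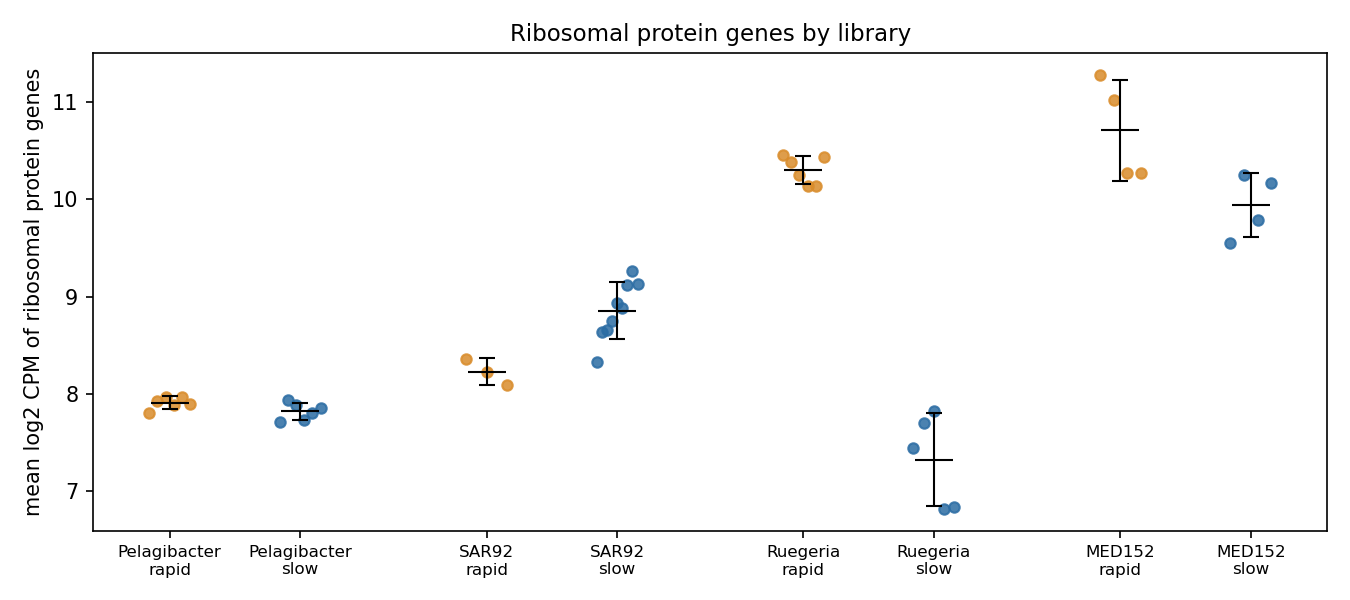
Mean log2 CPM of the ribosomal protein genes in each library (points, y axis) by strain and phase, with mean and SD (black bars). In Ruegeria the mean is 10.3 in rapid and 7.32 in slow growth, whereas in SAR92 it is 8.23 in rapid and 8.86 in slow growth, with the 3 rapid libraries at the low end.

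The share of genes changed at least 2-fold was 0.161% in Pelagibacter, 0.359% in SAR92, 4.83% in MED152 and 57.6% in Ruegeria. With 1 strain of each kind there is no test across strains. In draws of 3 rapid and 3 slow libraries thinned to a mean of 24 counts per gene, the mean share was 0.138% in Pelagibacter, 0.80% in SAR92, 2.29% in MED152 and 62.9% in Ruegeria. On average 259.8, 1157, 953 and 1899 genes could be tested in these draws. Of the tested Pelagibacter genes, 408 in the authors' deposited table had a q-value under 0.05, of which 54 were among the 75 called here. In the authors' deposited table the numbers were 209 and 140 of 251 in SAR92, 2685 and 2184 of 2621 in Ruegeria, and 557 and 157 of 256 in MED152.

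**Figure D4:**
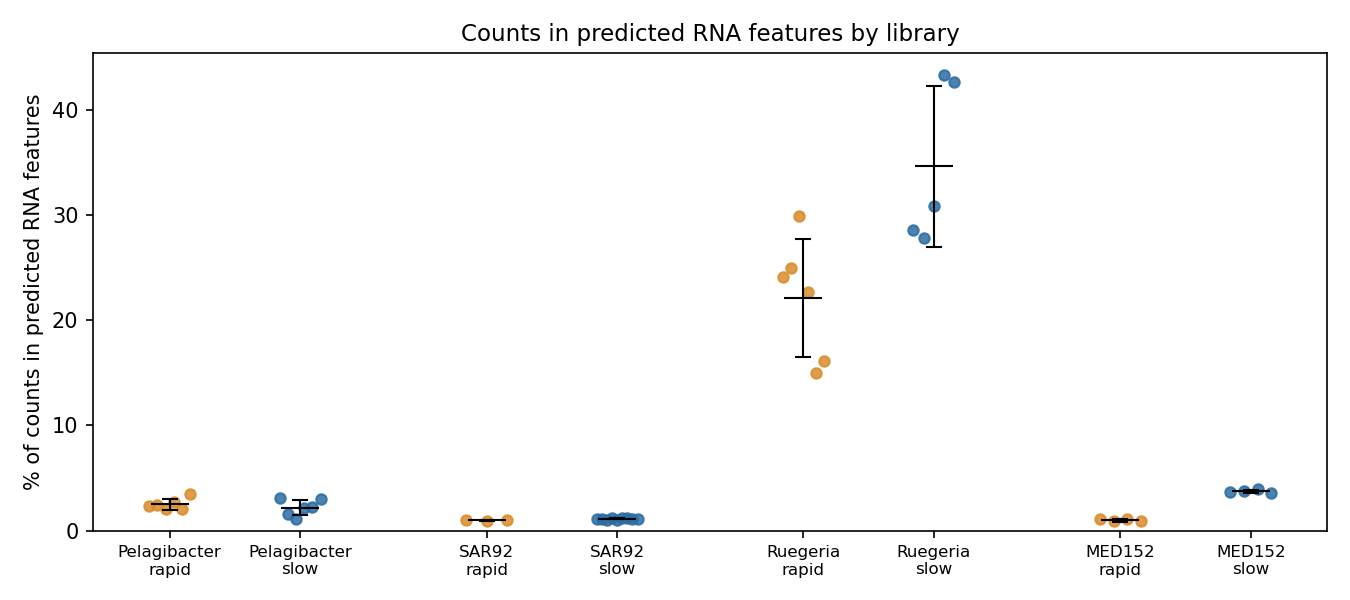
Share of all counts in predicted RNA features, which the gene tests leave out, in each library (points, y axis in percent) by strain and phase, with mean and SD (black bars). The mean goes from 22.1% in rapid to 34.7% in slow growth in Ruegeria and from 0.983% to 3.73% in MED152.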

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

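The tests of library scaling, the draws of 3 against 3 libraries, the share without libraries 137 and 141, the SAR92 list without each library and, for predicted RNAs, the tests of a general rise in MED152 and of low depth were chosen only after the data were seen. The other tests were chosen before.

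Far more genes changed in Ruegeria than in Pelagibacter, 57.6% against 0.161% at 2-fold or more. Depth and the number of libraries are argued against by the full data, where Pelagibacter had more libraries and 739.6 to 1194 counts per gene against 24 to 203.3, and 100% of simulated 2-fold changes were called there. In draws of 3 against 3 libraries thinned to a mean of 24 counts per gene, the lowest Ruegeria share was 59.97% and the highest Pelagibacter share 1.245%, over means of 1899 and 259.8 tested genes. Without the shallow libraries 137 and 141 the Ruegeria share was 54.97%, and with library totals 58.91%, which argues against these libraries and against scaling. A difference between the strains, or in how far their cultures slowed, may underlie the pattern and is untested, since the labels give no growth rate and the strains differ in every other respect too.

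With the SAR92 phase labels as given, ribosomal protein genes were higher in slow growth in SAR92 and lower in Ruegeria, 3.6 log2 units apart. With these labels exchanged the gap would be smaller. Scaling is argued against by a lowest SAR92 median of 0.5903 over 3 scalings, with a standard error of 0.1798 for the list score. A single library as the source of the direction is argued against by a lowest median of 0.5854 without each in turn. The calls did depend on single libraries: without rapid library 48 or 52, 17 and 5 genes of all those tested rose. With an estimated correlation the list did not pass in SAR92 (camera, adjusted p = 0.590). Exchanged phases in the SAR92 labels stay open: without the ribosomal list, list effects in SAR92 and Ruegeria had a Spearman correlation of −0.5928 over 27 lists (adjusted p = 0.00858, permutation test over 6 pairs of strains; lists are not independent). It was −0.58 between SAR92 and Pelagibacter (23 lists, adjusted p = 0.0137) and −0.27 between SAR92 and MED152 (25 lists, adjusted p = 0.226), where 13 lists had the same sign. A true opposite response of SAR92 could give the same value. The sample labels and count columns both hold 3 rapid and 9 slow libraries, and the sample titles place the rapid time point before the slow ones. These points argue against an exchange of whole phases. The columns carry no time point, so an exchange is not excluded and both stay open.

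Predicted RNAs, which no gene test used, held a mean of 2.34% of counts in Pelagibacter, 1.08% in SAR92, 27.8% in Ruegeria and 2.36% in MED152. In MED152 the share was 0.983% ± 0.132 in rapid and 3.73% ± 0.16 in slow growth, higher in 4 of 4 libraries (exact two-sided permutation p = 0.0286, the smallest possible, adjusted 0.0762 over 16 comparisons), and in Ruegeria 22.1% ± 5.6 and 34.7% ± 7.7, higher in 3 of 5 (exact p = 0.00866, adjusted 0.0346). A general rise of reads outside genes is argued against by a MED152 slow share of 0.1747% without the largest feature, under the 0.338% of rapid growth, and in Ruegeria by 46.83% of 205 features with a positive fold change. Low depth is argued against in MED152, where the 2 deepest slow libraries held 3.846%, but may add to the rise in Ruegeria, where they held 28.24%, nearer the rapid mean. Single features carried the rises, 352817 to 353243 on the plus strand in MED152 (0.645% to 3.56%) and chromosome 3163833 to 3164316 on the minus strand in Ruegeria (10.7% to 20.7%).

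The libraries were regrouped to see how many genes other splits call. The real split called the most in Pelagibacter (75 genes, highest other split 16, as large in 1 of 100) and Ruegeria (2621, highest other 4, 1 of 100). It did so in MED152 too (256, highest other 2, 1 of 35). Splits that mix the phases carry the phase effect into the spread, which lowers their calls. Libraries of 1 culture or time point may also not be independent, so these counts do not exclude chance. In SAR92, with 251 genes, 2 of 100 splits called as many, and a split setting slow libraries 80, 84 and 88 apart called 278, which points to a structure of the samples beside the phases. As many lists were called in 2 of 100 splits in Pelagibacter (7 lists, highest other 7) and 25 of 100 in SAR92 (6, highest other 10). It was 13 of 100 in Ruegeria (13, highest other 15) and 16 of 35 in MED152 (3, highest other 8). Splits with unequal numbers of the phases carry part of the phase effect, and members of a list are correlated. For lists these counts therefore neither exclude chance nor show it. Against the 26 lists that differed between strains, draws of phases within strains gave at most 21 (as many as 26 in 1 of 100). Such draws test for any phase effect and not for a difference between strains. Unbalanced draws carry part of the real phase effects. The 21 lists therefore cannot tell whether the adjusted p-values of the interaction overstate the evidence.

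In 16 of 371 groups of libraries 1 library stood apart by Dixon's test, where chance gives about 5%. In Pelagibacter these were slow library 32, at 6.24 in the mean log2 CPM of two-component genes, and slow library 30, at 7.39 log2 CPM for SAR11_1240. In SAR92 they were slow library 56 at 5.74 log2 CPM for GB2207_03974, and slow library 88 at 6.31 for GB2207_08486 and 7.03 for GB2207_06528. In Ruegeria rapid library 121 stood apart in the share of its top gene, 6.19%, in the mean log2 CPM of ATP synthase genes, 10.5, and in SPO0728 and SPO3498, 13.4 and 13.5. Rapid library 113 did so for SPO0926 at 9.07, rapid library 117 for SPO3409 at 2.51, and slow library 141 for SPO3409 at 6.97, SPOA0392 at 5.21, and SPO2627 and SPO0765 at 2.03, the value of 0 counts. In MED152 slow library 173 had 2.92 log2 CPM for MED152_12844.

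The phase effect differed between strains for 26 lists by the interaction test; the differences below are between the highest and the lowest strain, in log2 units. Where SAR92 is one of them, the pair and the size take its phase labels as given, which stay open above. With its signs turned they would change: for light and carotenoids, at −0.41 in SAR92 and 0.16 in MED152, SAR92 would be the higher. SAR92 would then no longer be highest for translation factors, the TCA cycle, the respiratory chain or RNA polymerase. Nor would it be for phosphorus acquisition or nitrogen assimilation. Some pairs without SAR92 would change too, such as that for TRAP transporters, at 0.24 in SAR92 and −0.21 in Pelagibacter. Between SAR92 and Ruegeria they were 2.19 for translation factors, 3.44 for ATP synthase, 1.82 for the TCA cycle, 1.71 for the respiratory chain, 2.1 for RNA polymerase, 0.545 for thiamine, 0.646 for phosphorus acquisition and 0.53 for the glyoxylate bypass, each higher in SAR92. Higher in Ruegeria than in SAR92 were phage and gene transfer agent (1.48), two-component systems (1.11), flagella (2.88), mobile elements (0.682) and peptidases (0.22). Higher in Ruegeria than in Pelagibacter were sulfur and carbon monoxide oxidation (2.02), sigma factors (1.93), TRAP transporters (0.587) and regulators (0.528). Higher in Pelagibacter than in Ruegeria were glycolysis and Entner-Doudoroff enzymes (1.77), DNA replication and division (0.664) and iron acquisition (1.74). MED152 exceeded Ruegeria in storage polymers (0.655) and the proteins matched by the transfer RNA list (1.39), and SAR92 in light and carotenoids (0.563). It lay below Ruegeria in polysaccharide degradation (0.532) and below SAR92 in nitrogen assimilation (0.536).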

How the results depend on the processing

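The predicted RNAs kept, both identical libraries kept, low-depth libraries left out, lists by library totals and without each library, strain differences without Ruegeria, without each library and with libraries weighted by strain, any-fold shares and draws of 3 against 3 libraries were chosen after seeing the data; the other settings were chosen before. Summary values stayed within 1.5 times their main value in 224 cases and moved further in 54. For lists 394 cases kept their call and 74 lost it. For named genes 2867 kept their side of the threshold, 294 lost and 25 gained a call. Genes called neither in the main fit nor in the alternative count as kept even where their sign changed. For strain differences 1210 kept their call and 35 lost it. Simulated 1.5-fold changes were called least often in Ruegeria and MED152, 14% and 12%. There the biological coefficient of variation was 27.1% and 25.5%, against 8.93% in Pelagibacter and 11.4% in SAR92, and the effects of depth and spread were not separated.

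Scaled by library totals, 264 genes were higher and 6 lower in Pelagibacter, and 154 were lower in SAR92, because this scaling shifts all genes together. Thinned to the smallest library, 21 genes were higher in Pelagibacter, and 726 higher and 752 lower in Ruegeria, with fewer counts tested. Without the low-depth libraries 173 and 193 edgeR called 1 gene higher and 0 lower in MED152, with 444 at an unadjusted p under the threshold and 42 higher and 28 lower by DESeq2, and the share at 2-fold fell to 0.0422%; this leaves 2 slow libraries. With DESeq2, 202 MED152 genes were lower. The cause was not tested.

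With an estimated correlation, camera called 0 lists in Pelagibacter, SAR92 and MED152 and 1 in Ruegeria, with 2, 0, 1 and 5 at an unadjusted p under the threshold, and fry, which tests a list on its own, called 2 in Pelagibacter and 24 in Ruegeria. Without Ruegeria 12 lists differed between strains. The share of genes changed was 0.402%, 3.77% and 10.9% at 1.5-fold in Pelagibacter, SAR92 and MED152, and 6.03%, 11.3% and 11.3% at any fold. In thinned draws it was 0.564% in SAR92 and 3.11% in MED152 for 2 against 2 libraries, and 0.80% and 2.29% for 3 against 3.

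Leaving out each library gave 20 to 39 genes higher, 27 to 55 lower and 3 to 7 lists in Pelagibacter, 5 to 203 higher, 25 to 145 lower and 3 to 7 lists in SAR92, 3 to 174 higher and 0 to 171 lower in MED152, and 1220 to 1292 higher and 1286 to 1344 lower in Ruegeria. Among named genes 2 changed sign and no longer passed: SAR11_0053 by library totals at 0.0175 (adjusted p = 0.896) and SPO1300 thinned at 0.00711 (adjusted p = 0.981). Among all called genes 3 changed sign in Pelagibacter by library totals, and in Ruegeria 8 when thinned, 2 with chromosome and plasmid apart and 3 without the low-depth libraries.

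No paired analysis was possible because the count columns carry library numbers and no replicate number. For the same reason the settings with time point as a factor, without each time point or replicate number, with the fifth SAR92 time point as rapid, and comparisons of time points within a phase were not run. Keeping ribosomal RNA features was not run, as no feature names one, nor was a pseudocount setting, as counts were tested.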

Other observations

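The runs of neighbouring genes were chosen after their values were seen; the correlations of same-named genes were chosen before.

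Where at least 5 neighbouring tested genes on 1 strand passed the edgeR test in the same direction, 92 runs were found, 86 in Ruegeria and 6 in MED152. SAR92 was not searched for runs, because its positions restart on unnamed contigs. In Ruegeria, 7 genes from SPOA0392 to SPOA0399 (plasmid 441633 to 446620, plus strand), which include R body proteins, known in other bacteria as coiled protein ribbons, had a median log2 fold change of 5.12. A formate dehydrogenase run of 7 genes (SPO1793 to SPO1799, chromosome 1908913 to 1916594, minus strand) had 4.33, and 5 genes around a carbon monoxide dehydrogenase (SPO2397 to SPO2401, 2543341 to 2552134) had 4.02. In other runs that rose, 6 genes with peptide, opine and nickel ABC transporters (SPO1542 to SPO1552) had a median of 4.21, and 10 with sugar transport and acetoin genes (SPO3783 to SPO3794) 3.64. The medians were 2.73 for 14 with pyrroloquinoline quinone and quinoprotein ethanol dehydrogenase genes (SPO1500 to SPO1514), 3.01 for 5 of glycerol-3-phosphate transport (SPO0236 to SPO0240), and 2.31 for 6 with phenylacetate and TRAP transport genes (SPO0734 to SPO0739).

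Runs that fell in Ruegeria included 9 genes of the 2-oxoglutarate dehydrogenase and succinyl-CoA synthase region (SPO0340 to SPO0347, 351721 to 362106), with a median of −2.69, and 6 genes of the sodium-translocating NADH-quinone reductase on the plasmid (SPOA0028 to SPOA0033, 24898 to 30744), with −1.95. Other runs that fell hold transporter genes, with medians of −2.44 for 5 of branched-chain amino acid ABC transport (SPO1935 to SPO1939), −1.77 for 5 with a xylose ABC transporter (SPO0861 to SPO0865) and −1.56 for 9 with a glutamate and glutamine ABC transporter (SPO0514 to SPO0522). They were −1.25 and −1.24 for 7 and 5 with oligopeptide ABC transporters (SPO3774 to SPO3780 and SPO3534 to SPO3538). Of all 225 ABC transporter genes tested in Ruegeria 93 rose and 66 fell (92 and 66 adjusted over the list alone), and camera did not call the list (adjusted p = 0.367). In MED152, 5 genes with rplJ, rplA, rplK, nusG and secE (MED152_04820 to MED152_04840, 1071853 to 1074354) had a median of −1.53 and 6 with a TonB-dependent receptor and xylose isomerase (MED152_05155 to MED152_05180, 1156291 to 1164715) −1.22. In MED152 these calls rest on single libraries, as for that strain's other calls. Of the 327 Ruegeria plasmid genes tested 142 rose and 62 fell, with a median of 0.44. The plasmid's share of gene counts was higher only in the shallow slow libraries 137 and 141, at 7.72% and 8.04%. It was 4.17%, 4.57% and 4.32% in slow libraries 125, 129 and 133, against 4.21% to 4.89% in the rapid ones. The hypothetical gene SPO3085 was the most abundant in slow libraries 125, 129 and 133, with 15.55%, 11.55% and 15.85% of gene counts.

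Antisense features in Ruegeria held 1.93% ± 0.46 of counts in rapid and 8.71% ± 3.61 in slow growth (SD, n = 6 and 5, exact two-sided permutation p = 0.00217, adjusted 0.0242 over 16 comparisons), higher in 5 of 5 slow libraries. The shallow libraries 137 and 141 held 11.9% and 13.1%, against 5.37% to 7.49% in the other slow ones, so the mean rise rests partly on them. A feature opposite SPO3689 (3898675 to 3899200, minus strand) went from 0.301% to 4.76%, and another feature (4013580 to 4014425, minus strand) from 1.95% to 0.0951%. With no statement on strand, reads of an antisense feature and of its gene cannot be separated. In SAR92 the share of predicted RNAs was 0.979% ± 0.035 in rapid and 1.11% ± 0.06 in slow growth (n = 3 and 9; exact p = 0.00455, adjusted 0.0242), higher in 9 of 9, and in Pelagibacter 2.50% ± 0.54 and 2.19% ± 0.75 (n = 6 and 6; exact p = 0.431).

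A hypothesis is that genes of the same name changed alike in different strains beyond the ribosomal proteins. Over all shared names, ribosomal proteins included, 31 of 39 genes called in both Ruegeria and MED152 moved the same way (335 shared). It was 8 of 20 between Pelagibacter and Ruegeria (415 shared) and 1 of 2 between Pelagibacter and MED152 (307 shared). These counts were not made without the ribosomal proteins, so they do not bear on the hypothesis. The Spearman correlation of fold changes across genes outside that list was 0.1478 between Ruegeria and MED152 (283 genes, permutation p = 0.0127, adjusted 0.038 over 3 comparisons). The correlation was 0.1276 between Pelagibacter and MED152 (258 genes, permutation p = 0.04, adjusted 0.06), and 0.08513 between Pelagibacter and Ruegeria (366 genes, permutation p = 0.104, adjusted 0.104). Genes are not independent replicates, so these values may overstate the evidence, and none exceeds a weak relation.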
